A study of Mus musculus and Homo sapiens with 56 samples.

How the data were processed

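The deposited processed files covered RNA-seq of WT and D395A mouse embryonic stem cells (2 libraries each), m6A RNA immunoprecipitation of chromatin RNA from the same genotypes, and m6A immunoprecipitation of HEK293T cells with shGFP, shALKBH5 or shFTO (2 lists each). Groups were taken from the sample labels. The 34 chromatin immunoprecipitation samples were not analysed here.

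Per the labels, the authors used FastQC, Trimmomatic 0.33.0, HISAT2 2.1.0, Picard 2.16.0, SAMtools 1.7, MACS2 2.1.1, Bowtie2 2.3.4.1, featureCounts 1.6.3 and edgeR 3.22.5 with builds hg38 and mm10, without saying which step used which tool. The RNA-seq file holds raw read counts per gene as deposited, with exon coordinates and exonic length in the layout of featureCounts, and the strand setting of the counting is not given. The name of 1 count column differs in 1 character from D395A and was taken as D395A replicate 1. Gene names, exons and strands came from the count table itself. The peak lists are deposited in the narrowPeak layout of MACS2. Their score column, as deposited, is an integer equal to 10 times the -log10 q, except in the D395A mouse list, where it is 10 times the -log10 p. Fold enrichment of immunoprecipitate over control at the summit is given as deposited, in the MACS2 layout. The -log10 p and -log10 q of each peak are also as deposited, and the smallest values show a threshold of 0.05 on q, or on p in the D395A mouse list. The WT mouse list stands for 2 immunoprecipitated and 2 input libraries, and how these were combined is not given in the sources used here. The 2 unlabelled further columns of that list were not used.

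Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (17778 of 52459, of which 21095 had no count in any library), scaled with TMM (factors 0.961 and 0.97 in WT, 1.034 and 1.038 in D395A) and compared with the edgeR quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use these scaled library sizes. The common dispersion was 0.003, a biological coefficient of variation of 5.5%. A chi-square per degree of freedom of 2.64 between WT replicates and 6.32 between D395A replicates shows spread beyond counting error in both groups. The 23 gene lists and the rules below were fixed before the data were examined. Lists were compared with all other tested genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation.

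Genes were named by rule: Mettl3, then in each direction the 12 called genes with the largest change, a mean of at least 1 CPM and both D395A libraries on the same side of both WT libraries. Then followed up to 4 called members per list with the smallest adjusted p, and in each direction 6 called genes with a WT peak and no D395A peak. For peaks, the rule named the 8 genes with the most peaks of a single list, and per knockdown and direction the 8 regions of best rank, of which the text gives a part. Other list members, the chromosome Y genes, Mat2a, Ston1 and Ust were named after their values were seen.

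Exonic overlap between genes on opposite strands was computed from the coordinates of the count table. Peaks were intersected with bedtools 2.31.1, counting 1 bp or more, and assigned to genes by overlap with the gene body. Observed overlap was set beside 100 random placements of D395A peaks within genes. HEK293T peaks were merged into regions, and a region was gained when both knockdown lists and neither shGFP list held it, and lost in the reverse case. Other splits of the same lists, 100 simulated sets of lists (observed calls exchanged at random within each region) and other control pairs gave the background. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

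The code was tested on simulated data. Of 50 genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, 60%, 66%, 96% and 92% were called, and 5.76% of calls were unchanged genes. The list that was shifted was called with the preset correlation and had an adjusted p of 0.0918 in camera with an estimated correlation. All 640 planted regions were recovered. Alternatives were DESeq2 1.42.0 size factors and its Wald test, upper quartile scaling, other count filters, the edgeR exact test, limma-voom, a replicate block, fry, each replicate left out, the top-ranked part or the same number of top-ranked peaks, 50% overlap, exon assignment and no covariates. With a replicate left out, the lone library of its group is assumed to vary like the other group. No genome sequence or human annotation was at hand, so the sequence motif of m6A sites was not searched and HEK293T regions carry no gene names.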

Results

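The series joins mouse embryonic stem cells and human HEK293T cells, an embryonic kidney line, and asks how N6-methyladenosine (m6A) on RNA at chromatin relates to the repressive histone mark H3K9me2. The mouse line was E14TG2a, kept with LIF and inhibitors of MEK and GSK3β, either wild type (WT) or carrying the D395A substitution in the catalytic centre of METTL3, the enzyme that writes most m6A in messenger RNA. In HEK293T cells, lentiviral short hairpin RNAs lowered ALKBH5 or FTO, demethylases that act on m6A, with a hairpin against GFP as control. Values were analysed for 22 of the 56 samples: RNA-seq counts of 2 WT and 2 D395A libraries, m6A peak lists of WT and D395A mouse cells, and m6A peak lists of 2 replicates each of shGFP, shALKBH5 and shFTO cells. The 34 chromatin immunoprecipitation samples were not analysed here. The RNA-seq libraries held 13953069 and 19246342 counts in WT replicates 1 and 2, and 12743677 and 18151353 counts in D395A replicates 1 and 2.

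The first comparison asked which RNAs differ between D395A and WT cells. D395A cells had less RNA of the naive pluripotency factors Tbx3 and Tcl1 and of Lncenc1, a long non-coding RNA of naive stem cells, and more of Dppa3 (Stella), the pioneer factor Foxa2, the neural factor Pax6 and the imprinted genes H19 and Peg3. Tbx3 fell from 528 ± 11 to 25.5 ± 1.67 CPM (counts scaled to library size; mean ± SD, n = 2 libraries per group here and below), and Tcl1 fell from 123 ± 1.3 to 4.47 ± 0.075 CPM. Foxa2 rose 108-fold, from 0.267 ± 0.150 to 27.8 ± 1.35 CPM, and H19 rose from 0.888 ± 0.118 to 41.7 ± 1.99 CPM. Of 17778 genes tested, 6550 were higher and 6093 were lower in D395A at an adjusted p below 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 3552 of the former and 2107 of the latter differed at least 2-fold. Replicates correlated at 0.994 in WT and 0.992 in D395A on the log2 CPM scale across genes, against 0.873 to 0.888 between the groups. Against a fold change of 2 instead of no change, a threshold added after the data were seen, 2733 genes were higher and 1294 lower. The labels do not say whether the replicates came from separate cultures, so these p-values measure only the spread between the libraries. These p-values cannot separate the substitution from other differences between the lines or in how their libraries were handled.

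Mettl3 itself was measured at 36.2 and 35.5 CPM in the WT libraries and at 30.6 and 33.9 CPM in the D395A libraries. Its log2 fold change was -0.15 ± 0.08 (SE), with an adjusted p of 0.114 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. A substitution of 1 codon leaves the transcript countable, so these counts do not check the genotype, and 21.1% of Mettl3 exonic bases are overlapped by a gene on the opposite strand.

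Genes that share exonic bases with a gene on the opposite strand stood apart in the D395A libraries. The median log2 fold change was -0.07 over the 12377 tested genes with no such overlap, 0.09 over the 4204 genes with up to 25% of exonic bases overlapped, 2.11 over the 284 genes with 50 to 90% and 5.26 over the 203 genes with more than 90%. In that last class 74.9% of genes were called at least 2-fold higher in D395A and 3.9% at least 2-fold lower. These shares were 15.6% and 14.1% with no overlap and 23.4% and 7.3% with up to 25%. Over the 710 genes with 25 to 50% overlap they were 44.5% and 5.2%, with a median log2 fold change of 0.73. The signal of the partner over the overlap was taken as its CPM times the overlapped share of its exonic bases. In 63 genes with at least 50% overlap this signal averaged 30 CPM or more. Their own CPM was a median 0.98% and 0.5% of it in the WT libraries, and 32.4% and 26.7% in the D395A libraries. Without overlapped genes, a setting added after the data were seen, 4031 genes were called higher and 4647 lower, the reverse of the balance over all genes, and 1931 were at least 2-fold higher and 1751 at least 2-fold lower. Values of overlapped and antisense genes are therefore uncertain in this comparison. Both D395A libraries differed from both WT libraries in this respect. A difference in library handling or counting cannot be told apart from genotype, also for genes without overlap and for the gene lists below. Exons that lie only within introns of an opposite-strand gene were not counted as overlapped. An overlap of 10% or more is given where a gene's change is described, though smaller overlaps are not free of the shift. Genes described below with less are Tet2 (0.25%), Mecom, Dnmt3a, Shmt2, Rbm15b, Tbx3, Fn1, mt-Nd6, Eomes, Kdm7a, Slc2a1, Fto, Eif2ak2, Ncam1, Pfkp (5.58%), H19, Jun (7.28%), Rtl1 (8.12%) and Sall4 (9.5%).

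**Figure D1:**
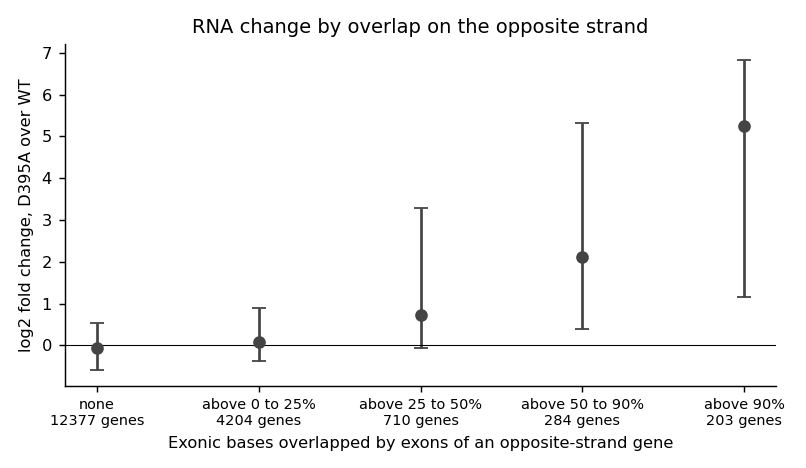
Median log2 fold change of D395A over WT (points) with the quartiles of the genes (bars), by the share of a gene's exonic bases that exons of an opposite-strand gene overlap. The median lies at -0.07 for genes with no overlap and at 5.26 for genes overlapped over more than 90% of their exons.

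Among the 12 genes with the largest rise, all were at 0 counts in both WT libraries, and 10 are overlapped on the opposite strand, from 8.12% of exonic bases in Rtl1 to 100% in Gm12744 and Gm44313. Gm12744 stood at 11.9 and 9.78 CPM in D395A (at least 114-fold higher, taking 3 counts over the group as the floor; floors and intervals cover counting error only). Gm26733 (97.9% overlap) stood at 10.4 and 9.30 CPM, Gm44357 (83.1%) at 13 and 6.43 CPM and the retrotransposon-derived imprinted gene Rtl1 at 11.1 and 5.64 CPM. Gm26790 (83.5%), Gm15886 (51.2%), 5830462I19Rik (29.1%), Gm26636 (98.2%), Gm16069 (46.2%) and Gm44313 (100%) completed the overlapped genes, with bounds from 58.8-fold to 79.2-fold. Vtn and Car4 have no such overlap. Vtn, which encodes the adhesion protein vitronectin (mm10 chromosome 11, 78499091 to 78502324), stood at 8.22 and 8.93 CPM in D395A, at least 92.2-fold higher. Car4, a membrane carbonic anhydrase, stood at 7.0 and 7.18 CPM, at least 75.8-fold higher.

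None of the 12 genes with the largest fall is overlapped. Pramel6, of a gene family expressed in germ cells and early embryos (chromosome 2, 87506565 to 87510872), fell from 11.1 and 8.96 CPM to 0 counts in both D395A libraries, at least 105-fold lower. The olfactory receptor genes Olfr153 and Olfr837 fell from 4.45 ± 0.910 and 3.68 ± 0.190 CPM to 0, at least 48.6-fold and 38.9-fold lower. AC124581.4, AC162931.1, Gm14833, AC124397.1, Gm12171, G430049J08Rik and Xlr5b also fell to 0, with bounds from 22.3-fold to 54.2-fold. Gm13128 and Cacng5, which encodes a calcium channel subunit, kept 1 and 2 counts, at 0.0380 ± 0.0538 and 0.0532 ± 0.0752 CPM against 14.3 ± 0.827 and 11.7 ± 0.908 CPM in WT. Pramel6, Olfr and Xlr5b belong to families of similar genes whose reads the counting may have shared out. A further selection was made after the data were seen. It took genes with a mean of at least 10 CPM, no exonic overlap on either strand and no exon inside an opposite-strand gene. It also required more than 3 counts in each group, which leaves out genes near 0 in a group. The leading rises were Foxa2, the kinesin Kif26a (1.10 ± 0.186 to 112 ± 5.90 CPM), Gna14, Sema3e, Cyp1b1 and Igfbp5. The leading falls of that selection were the homeobox gene Tlx2 (25.8 ± 0.635 to 0.243 ± 0.194 CPM), the serotonin receptor gene Htr5a, Clgn, Gm33027 and Slfn8, with Lncenc1 (chromosome 13, 97434970 to 97497007) next at 730 ± 3.92 against 19 ± 2.73 CPM.

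The RNA was also lower across chromosome 8. Genes with a mean of at least 10 CPM entered the chromosome comparison. The median log2 fold change of the 565 such genes on chromosome 8 was -0.42, against -0.04 for the other autosomes. All 13 of its windows of 10 Mb lay below the latter value. The difference was -0.39 in D395A replicate 1 and -0.38 in replicate 2. On chromosome Y the median was -1.28 over only 7 genes (quartiles -2.16 to -0.15). Eif2s3y, a translation factor gene, fell from 87.1 ± 2.37 to 14.8 ± 0.115 CPM, Uty from 57.9 ± 6.31 to 13.1 ± 2.02 CPM and Ddx3y from 79.2 ± 5.48 to 17.5 ± 1.15 CPM, while the demethylase gene Kdm5d rose from 3.76 ± 0.143 to 6.0 ± 0.842 CPM. Chromosome 6 went the other way, with a median of 0.17 and 40.7% of its 482 genes lower, the highest median of any autosome, followed by chromosome 19 at 0.08. Without chromosomes 8 and Y, again a later choice, 11886 genes were called.

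**Figure D2:**
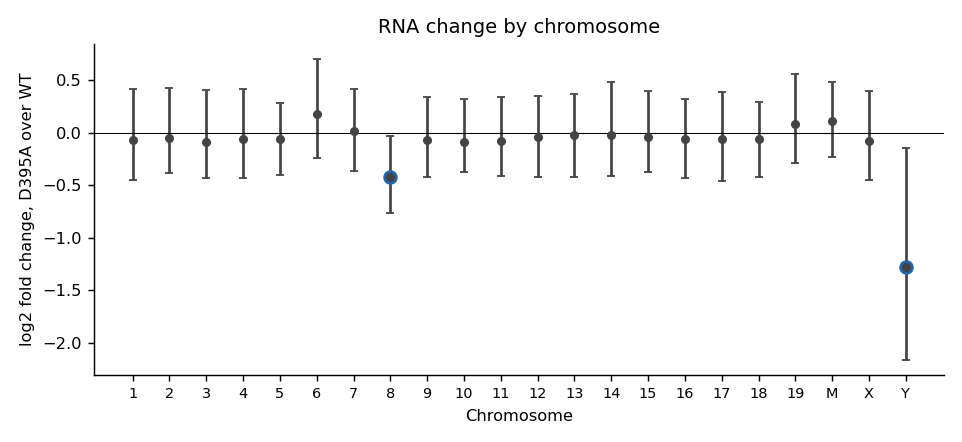
Median log2 fold change of D395A over WT by chromosome (points, with the quartiles of the genes as bars; chromosomes 8 and Y marked in blue). Chromosome 8 lies at -0.42 and chromosome Y, with 7 genes, at -1.28, while chromosome 6 has the highest autosomal median, 0.17.

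Gene lists fixed before the data were examined were then compared with all other tested genes. Of the 23 measured naive pluripotency genes, 17 fell and 3 rose. Among them Nanog fell from 693 to 410 CPM, Klf4 from 415 to 162 CPM, the signalling co-receptor gene Tdgf1 (Cripto) from 501 ± 6.74 to 61.4 ± 5.0 CPM and Esrrb from 966 to 540 CPM. Dppa3 rose 17.1-fold, from 5.04 ± 0.156 to 87.2 ± 12.8 CPM, with Klf2 and Socs3 the other members that rose. Sox2, Nr0b1 and Sall4 did not pass. Of 29 imprinted genes, which are expressed from a single parental copy, 21 rose and 2 fell. Peg3 rose from 44.9 ± 2.48 to 281 ± 9.58 CPM, Sgce from 8.86 ± 1.65 to 68.6 ± 0.823 CPM, and the maternally expressed H19, with 5.94% overlap, 47.3-fold, while the growth regulator Grb10 fell from 161 ± 3.21 to 45.5 ± 2.3 CPM. Both lists stood apart in camera with a preset correlation (Benjamini-Hochberg adjusted p = 0.00124 for naive pluripotency and 0.00221 for imprinted genes), and neither did with an estimated correlation (adjusted p = 0.967 for each, raw p = 0.0468 and 0.171). Among members with no opposite-strand overlap, 14 of 19 naive pluripotency genes fell and 3 rose, and 12 of 17 imprinted genes rose and 1 fell. Without overlapped genes camera gave 0.0082 and 0.00678 for these lists, again with Benjamini-Hochberg adjustment.

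**Figure D3:**
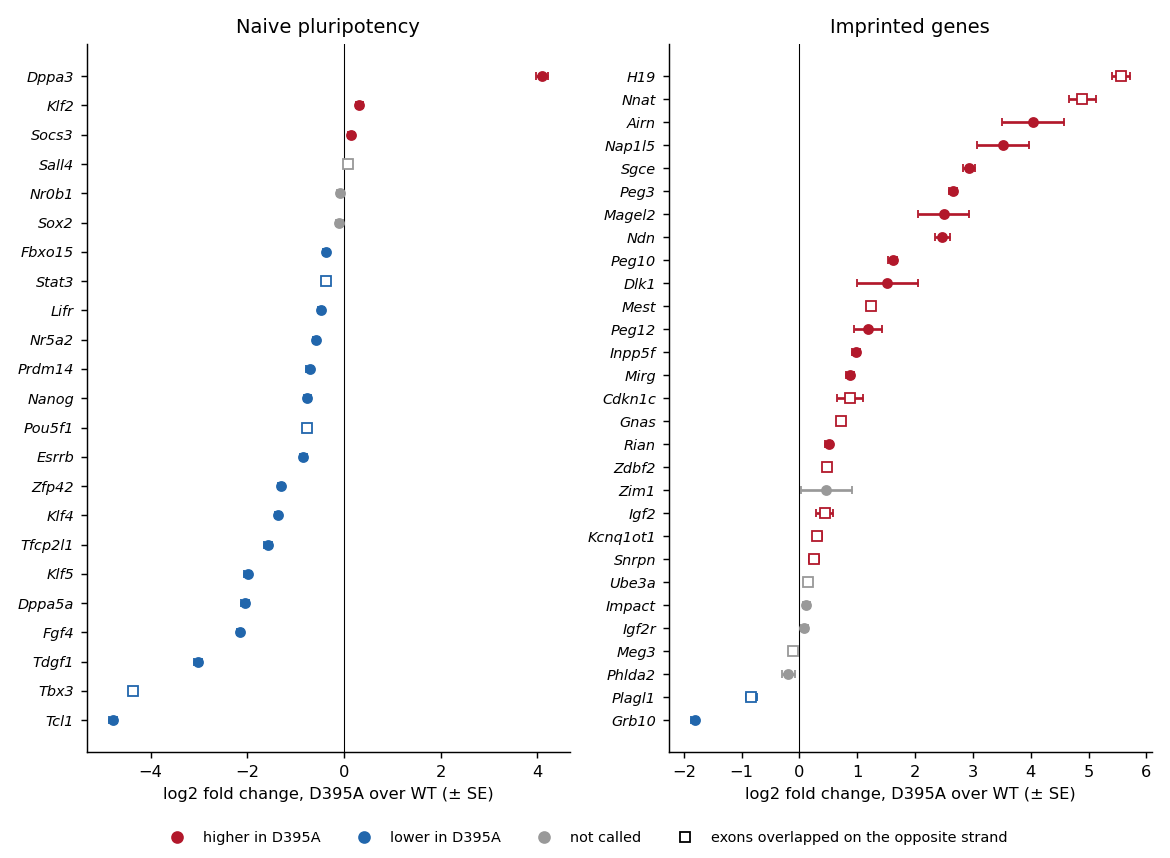
Log2 fold change of D395A over WT (± SE, 2 libraries per group) of each tested gene of the naive pluripotency and imprinted lists, coloured by call at an adjusted p below 0.05 (open squares, exons overlapped on the opposite strand). Most naive pluripotency genes lie below 0, with Dppa3 at 4.1, and most imprinted genes lie above 0, with Grb10 at -1.82.

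The enzymes of the m6A and H3K9 pathways changed in both directions. Of 24 m6A machinery genes, 10 rose, 5 fell and 9 did not pass. The reader Ythdf2 rose from 166 ± 3.46 to 339 ± 11.6 CPM (log2 fold change 1.03 ± 0.06 SE), the writer subunit Virma rose from 134 ± 4.90 to 217 ± 7.20 CPM, and Rbm15b and the nuclear reader Ythdc1 rose 1.46-fold and 1.43-fold. The demethylase genes Alkbh5 and Fto did not pass, at log2 fold changes of 0.12 each. Of 18 H3K9 methylation enzymes and readers, 8 rose and 7 fell, or 4 and 4 of the 10 with no opposite-strand overlap. The methyltransferase gene Suv39h1, with 14.6% overlap, rose from 28.8 ± 0.638 to 93.2 ± 4.69 CPM, Mecom rose from 1.88 ± 0.0836 to 12.2 ± 0.182 CPM, Ehmt2 (G9a) rose 1.56-fold and its partner Wiz, with 22.8% overlap, 1.68-fold. Of 11 H3K9 demethylase genes, 4 rose and 6 fell. Kdm3a fell from 324 ± 0.208 to 166 ± 4.47 CPM and Kdm3b, with 24.6% overlap, from 425 ± 1.67 to 284 ± 10.8 CPM, while Phf8 rose from 86.6 ± 1.27 to 299 ± 29.6 CPM and Kdm7a from 36.3 ± 3.11 to 76.4 ± 5.27 CPM. Among 13 DNA methylation genes, 6 rose and 4 fell: the 5-methylcytosine oxidase gene Tet2 fell from 828 ± 0.202 to 120 ± 8.39 CPM and the imprint protector gene Zfp57 fell 2.31-fold, while the de novo methyltransferase gene Dnmt3a rose from 39.0 ± 1.11 to 148 ± 6.16 CPM and Mbd3 rose 1.78-fold. None of these lists passed in camera, with adjusted p values of 0.693, 0.908, 0.774 and 0.938 in that order (Benjamini-Hochberg).

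Lineage lists were mixed as well. In the formative and primed epiblast list 7 genes rose and 8 fell of 18. The Nodal pathway gene Lefty2 fell from 125 ± 5.26 to 6.88 ± 1.02 CPM and Etv4 fell 10.0-fold, while Sall2 rose 8.40-fold and Sox4, with 54.6% overlap, 4.14-fold. Endoderm genes split into 6 that rose and 7 that fell of 17, or 3 and 7 of the 11 with no opposite-strand overlap. Foxa2 and Dab2 (4.86-fold) rose, and the basement membrane gene Lama1 fell from 347 ± 6.25 to 38.9 ± 3.64 CPM, as did Sparc, 2.05-fold. In mesoderm 5 rose and 7 fell of 13, and both T (Brachyury), from 16.5 ± 3.35 to 0.194 ± 0.0486 CPM, and Eomes, from 13.9 ± 0.477 to 2.08 ± 0.0779 CPM, fell, as did Pdgfrb, 1.94-fold, while Mesp2 rose 6.24-fold. In neuroectoderm 7 rose and 4 fell of 14. Pax6 rose from 0.375 ± 0.00144 to 15.6 ± 0.701 CPM and Sox11 rose 7.43-fold, while Stmn2 and Ncam1 fell 3.68-fold and 3.13-fold. Trophectoderm genes rose in 9 and fell in 3 of 16 cases, with Fgfr2 22.2-fold, Rhox6 16.1-fold and Peg10 3.05-fold higher and Tead4 5.28-fold lower. Of 13 fibroblast or feeder genes, 6 rose and 4 fell, or 3 and 3 of the 8 with no opposite-strand overlap. Fn1 (fibronectin) fell from 2745 ± 6.79 to 1406 ± 146 CPM, while Col5a2 rose 9.75-fold, and Timp3 and Fbn1, with 21.3% and 20.1% overlap, 6.74-fold and 2.29-fold. Of 15 genes of the 2-cell-like state, 7 rose and 1 fell, led by Zscan4d, from 4.82 ± 0.473 to 17.8 ± 2.02 CPM, with Zscan4e, Zscan4c and Zscan4f 2.17-fold, 1.75-fold and 1.88-fold higher, though reads may have been shared out among these similar copies. The camera adjusted p of that list was 0.213, and 0.0453 without overlapped genes, against 0.173 to 0.967 in the other camera settings (Benjamini-Hochberg). Of 25 germline genes, 8 rose and 11 fell. The piRNA factor Rnf17 fell from 189 ± 2.95 to 12.6 ± 0.0213 CPM, and Hormad1 and Dazl fell 6.25-fold and 2.63-fold, while Tdrkh, with 36.7% overlap, rose 6.35-fold. Of 25 tested Hox genes, 8 rose, 6 fell and 11 did not pass, while 4 rose and 6 fell of the 20 with no opposite-strand overlap. Hoxa2 rose 15.1-fold, while Hoxc12 fell from 13.7 ± 1.49 to 0.437 ± 0.242 CPM and Hoxc13 fell 2.79-fold.

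Among stress and metabolic lists, cholesterol synthesis moved in a single direction: 14 of 21 genes rose and none fell. Dhcr7, the last enzyme of the pathway, rose from 142 ± 7.86 to 271 ± 10.5 CPM, and Mvd and Sc5d rose 1.37-fold and 1.35-fold. The camera adjusted p for this list was 0.119, and it was 0.043 without D395A replicate 1 and 0.0478 without D395A replicate 2, against 0.0502 to 0.967 in the other camera settings (Benjamini-Hochberg). Of 23 p53 targets, 14 rose and 6 fell. Perp rose 2.85-fold, Tnfrsf10b 2.23-fold and Aen 1.56-fold, and Trp53 itself fell from 387 ± 15.5 to 207 ± 12.1 CPM. In the integrated stress response 8 rose and 9 fell of 22, with Ddit4 2.37-fold higher and Cth, Nupr1 and Shmt2 3.58-fold, 1.95-fold and 1.69-fold lower. Interferon response genes numbered 3 higher and 4 lower of 12. The antiviral genes Xaf1, from 88.6 ± 0.772 to 5.82 ± 0.487 CPM, Oas1a and Eif2ak2 fell, and Bst2 rose 4.29-fold. Of 15 immediate early genes, 7 rose, among them Jun (5.01-fold) and Srf (1.82-fold), and 5 fell, among them Ier2 (1.99-fold) and Nr4a1 (1.97-fold). Of 23 glycolysis genes, 10 rose and 6 fell: the glucose transporter genes moved apart, Slc2a1 from 165 ± 0.360 to 438 ± 13.5 CPM and Slc2a3 from 1664 ± 32.4 to 908 ± 35.5 CPM, with Bnip3, with 22.2% overlap, 2.90-fold higher and Pfkp 2.79-fold lower. Of 15 mitochondrially encoded genes, 6 rose and 5 fell, with mt-Nd6 3.18-fold, mt-Nd2 1.46-fold and mt-Nd1 1.40-fold higher, while the ribosomal RNA mt-Rnr1, depleted with other ribosomal RNA, was at 16.5 and 2.52 CPM in WT and at 1.07 and 0.372 CPM in D395A. Of 12 structural non-coding RNAs, 1 rose and 6 fell, among them Gas5 (1.79-fold), Snhg1 (1.48-fold), Snhg11 (1.58-fold) and Malat1 (1.27-fold, 12.6% overlap). None of these lists passed in camera over all 4 libraries. Among members with no opposite-strand overlap, 11 of 15 cholesterol synthesis genes rose and 0 fell, and 14 of 22 p53 targets rose and 5 fell. Over the 23 lists the calls were the same when adjusted over the list alone, except that 6 instead of 4 fibroblast or feeder genes were then called lower. Camera in limma called the Hox list when D395A replicate 2 was left out (Benjamini-Hochberg adjusted p = 0.0268, 0.593 to 0.967 in the other settings except fry). Median, mean and camera direction disagreed in sign for the H3K9 demethylase, DNA methylation, endoderm, integrated stress response, immediate early and mitochondrial lists.

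The next comparison asked whether RNAs that carry m6A in WT changed in D395A. Of the tested genes, 4651 held a WT peak and no D395A peak, 7168 held peaks in both lists, 2184 held only a D395A peak and 3775 held none. The median log2 fold changes were 0.17, 0.00, -0.15 and -0.04 in that order. Genes with a WT peak only rose in 1998 cases and fell in 1357 cases. The largest rises among them were Gm12744, Vtn, Gm26790, Gm26636, the B cell surface gene Cd72 (41.6% overlap, at least 46.8-fold) and Kdm6bos (34.0% overlap, at least 47.4-fold), all at 0 counts in WT, and only Vtn is not overlapped. Peaks were assigned to gene bodies without regard to strand, so it is uncertain whether the WT peaks of these genes, whose RNA was not counted in WT, belong to them. The largest falls were Pramel6, AC124581.4, Olfr153, AC162931.1, Gm14833 and Gm13128. With mean CPM and exonic length as covariates, log2 fold changes across genes differed from those of genes without peaks by 0.033 ± 0.041 (SE over genes, which are not independent replicates) for WT-only genes and by 0.239 ± 0.044 for genes with peaks in both lists, and by 0.254 ± 0.052 for genes with a D395A peak only, which lack a WT peak. The first difference was -0.106 without genes overlapped on the opposite strand, -0.051 with peaks assigned to exons, -0.183 without covariates and -0.006 without WT replicate 2, and the second was 0.048 ± 0.042, 0.077 ± 0.044, -0.339 and 0.202 in the same settings. That of genes with a D395A peak only was 0.03 ± 0.05, 0.04 ± 0.05, -0.287 and 0.223. With D395A peaks limited to a q below 0.05, a later choice, the differences were 0.067 ± 0.033 for WT-only genes, 0.244 ± 0.051 for genes with both and 0.418 ± 0.072 for D395A-only genes. Camera was run on the classes with a WT peak, and none passed, with Benjamini-Hochberg adjusted p values of 0.365 for WT-only genes, 0.882 for genes with peaks in both lists and 0.365 for these classes together.

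The m6A peak lists of the mouse cells addressed whether loss of METTL3 activity removes peaks. WT-only peaks included 16 in the synaptic scaffold gene Pclo, 14 in the spectrin gene Sptb, 13 in Necab1, 12 each in Trpm3 and the tau gene Mapt, 11 in Rgs22 and 10 each in Gm34933 and the Wnt co-receptor gene Lrp5, which held no D395A peak. Mapt RNA itself fell from 52.5 ± 2.15 to 2.22 ± 0.202 CPM. D395A peaks without any WT peak in the gene numbered 22 in the RNA-binding protein gene Msi2, 21 in Bcat1, 19 each in Erdr1, Tbc1d22a and Skap2, 18 in Fn1, 16 in Pnpt1 and 14 in Dtnb. Of 48445 WT peaks, 4906 (10.1%, exact 95% interval 9.86 to 10.4%) overlapped a D395A peak by at least 1 bp, and 13.5% of the 38823 D395A peaks overlapped a WT peak. Random placement of the D395A peaks within genes overlapped 3.84% of WT peaks on average over 100 draws (3.64 to 4.02%), while the observed D395A peaks that lie in genes overlapped 7.38%. Placement was uniform over gene bodies, introns included. A preference of both lists for exons could therefore raise the observed overlap without shared sites. Per gene, 14736 genes held a WT peak, 10680 a D395A peak and 7751 both, so 6985 genes (47.4%) held WT peaks alone.

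Among fixed lists, 26 of 39 Hox genes held a WT peak and 3 a D395A peak, while 17 and 22 of 24 m6A machinery genes did. These counts were not adjusted for RNA level. Over tested genes the median CPM was 7.15 with a WT peak alone, against 42.5 with peaks in both lists and 38.8 with a D395A peak alone. Only 25 of the 39 Hox genes had enough counts to be tested, against all 24 m6A machinery genes. With D395A peaks at a q below 0.05, the threshold of the WT list and a choice made after the data were seen, 0 Hox genes and 12 m6A machinery genes held a D395A peak. All but Kdm4d of the 11 H3K9 demethylase genes held peaks in both lists, and 4 (Kdm3a, Kdm3b, Jmjd1c and Kdm1a) held a D395A peak at that q. Of the H3K9 methylation enzymes and readers 16 and 15 of 18 held WT and D395A peaks, 6 of them at that q in D395A. Ehmt2 and Setdb2 held WT peaks alone. Of 23 naive pluripotency genes, 16 held a WT peak and 19 a D395A peak, or 12 at that q, with Nanog and Nr0b1 only in WT. Mettl3 held no WT peak and 1 D395A peak. WT peaks lay in exons in 35.3% and in introns in 29.9% of cases, and D395A peaks in 18.1% and 67.3%. Summits placed on a transcript fell within its first 200 exonic nucleotides for 2.6% of WT peaks not overlapped in D395A and for 15.4% of D395A peaks with a q below 0.05 outside the WT list. Among peaks that overlap the other list, the shares were 3.6% in WT and 9.9% in D395A at that q.

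The lists differ in how they were made. Each genotype has a single list, so no spread between replicates can be given. The WT list, from 2 pairs of libraries, ends at a q of 0.05, and the D395A list, from 1 pair, at a p of 0.05, with 5275 peaks (13.6%) at a q below 0.05. Restricted to these, 1025 WT peaks (2.12%) were overlapped, and 12335 genes held WT peaks alone. WT peak numbers run to 53814 with 5369 missing, while no number is missing from the D395A list. Of the 100 most significant D395A peaks none overlapped a WT peak, and 71.0% lay where WT numbers skip, stretches that make up 29.1% of the length between WT peaks and hold 13.6% of the D395A peaks with a q of 0.05 or more outside the WT list. If every missing WT peak beside a D395A peak overlapped it, 13.1% of WT peaks would be overlapped. That count takes only gaps between WT peaks of the same chromosome. It leaves out the mitochondrial genome, where the WT list holds no peak. The most significant D395A peak (chromosome 6, 72430409 to 72437792, fold enrichment 24.2 as the authors' list gives it) covers exons of Mat2a and reaches an exon of its neighbour Ggcx. The Mat2a product makes S-adenosylmethionine, the methyl donor for m6A. No WT peak was listed there, and WT peaks were listed next to it over Ggcx.

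**Figure D4:**
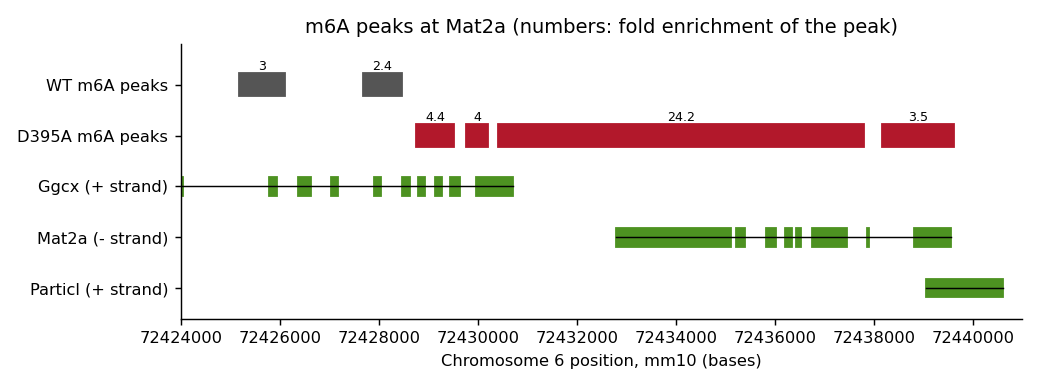
Deposited m6A peaks of WT (grey) and D395A (red) cells along mm10 chromosome 6 around Mat2a, with the exons of Mat2a and its neighbours in green and each peak's fold enrichment above it. The D395A peak of 24.2 covers most Mat2a exons, where the WT list holds no peak.

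In HEK293T cells the question was whether lowering an m6A demethylase adds m6A peaks. Regions are named by hg38 coordinates, with no gene annotation used. Lists held 19232.5 ± 689.4 peaks in shGFP, 18438 ± 3149.5 in shALKBH5 and 19262 ± 4181.8 in shFTO (mean ± SD, n = 2 lists), and an exact two-sided permutation test gave p = 1.0 for each knockdown, where 2 lists against 2 allow no p below 0.333. Of 28812 merged regions, 10548 (36.6%) were called in all 6 lists and 7238 in a single list. Lists of the same group shared 61.7 to 65.9% of regions, and lists of different groups 59.6 to 67.9%.

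In shALKBH5 cells, 506 regions were called in both knockdown lists and neither shGFP list, and 865 were lost in the same sense. Gained regions among those of best rank lay on chromosome 21 (8255610 to 8255956, fold enrichment 4.4 and 5.5), on chromosome 16 (11376224 to 11376790, 10.7 and 11.9) and on chromosome 6 (43348333 to 43348879, 6.8 and 6.8). Both shFTO lists also held the regions on chromosomes 16 and 6. By the poorer rank of the 2 lists, the 8 best gained regions stood only at 5523 to 9120, in lists of 16211 and 20665 peaks. The 8 best lost regions stood at 3124 to 6722, in shGFP lists of 19720 and 18745. The lost region of best rank lay on chromosome 13 (68152324 to 68153257, 24.0 and 21.5 in the shGFP lists), and both shFTO lists held it, as they did the lost region on chromosome X (130024801 to 130025297, 11.8 and 10.4). Other splits of the same 4 lists into pairs gave 712 and 254 regions, and 398 and 1009, so the real split did not exceed them. When each list was limited to the same number of top-ranked peaks, 551 regions were gained and 619 lost, against at most 545 and 456 in the other splits. With 1 list of a group left out, the counts gained were 1157 without shGFP replicate 1, 1160 without shGFP replicate 2, 3143 without shALKBH5 replicate 1 and 1386 without shALKBH5 replicate 2, and the counts lost were 2551, 2981, 1312 and 2433.

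In shFTO cells, 654 regions were gained and 693 lost. Gained regions of best rank lay on chromosome 11 (85503982 to 85504853, fold enrichment 12.3 and 22.7), chromosome 14 (96951868 to 96952601, 10.2 and 13) and chromosome 10 (37777737 to 37778767, 9.6 and 18.2). The first of these was also called in both shALKBH5 lists. By the poorer rank of the 2 lists, the 8 best gained regions stood only at 5716 to 9038, in lists of 16305 and 22219 peaks. The 8 best lost regions stood at 5785 to 8581 in the shGFP lists. The lost region of best rank, on chromosome 3 (156849041 to 156850137, 17.2 and 15.2 in the shGFP lists), was absent from all 4 knockdown lists. Others lay on chromosome 2 (65020914 to 65021393, 11.3 and 10.9) and chromosome 1 (210099827 to 210100361, 11.8 and 13.3). Other splits gave 1033 and 170 regions, and 167 and 1201. At the same number of top-ranked peaks per list, 673 were gained and 661 lost, against at most 486 and 470 in the other splits. With 1 list left out, 1535 and 1253 regions were gained without shGFP replicates 1 and 2 and 4165 and 1221 without shFTO replicates 1 and 2, and 2344, 2471, 903 and 2462 were lost. A real split among 3 cannot reach a share of 0.05 in either knockdown.

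**Figure D5:**
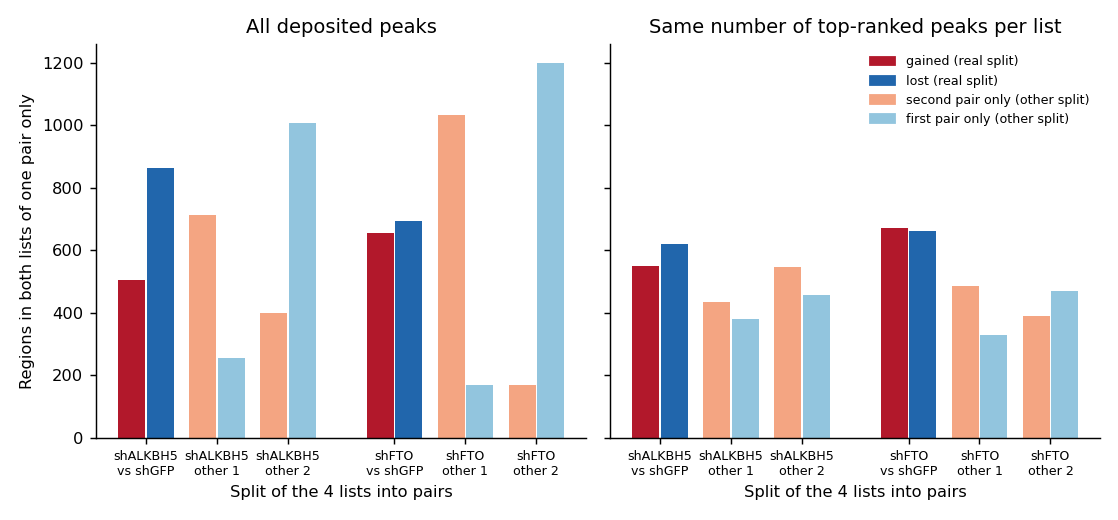
Regions called in both lists of one pair and in neither list of the other, for shALKBH5 and shFTO against shGFP (dark bars, gained in red and lost in blue) and for the other splits of the same 4 lists (pale bars). With all deposited peaks (left) the other splits reach 1201, and with the same number of top-ranked peaks per list (right) they reach 545, below the real counts of 551 to 673.

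Both knockdowns shared 141 gained and 328 lost regions, such as the lost region on chromosome 3. Lost lists of these sizes would share 20.8 regions if independent, which the shared shGFP lists are not, and no simulation was run for lost regions. Gained lists of these sizes would share 11.5 regions if independent. In 100 simulations, the observed calls were exchanged at random among the lists within each region, which kept its number of lists. With the shared shGFP lists as control, 150.2 regions were then shared on average (122 to 181). The shuffle draws on the observed regions themselves and treats each region separately. Its range therefore leaves out differences between whole lists. The simulated lists were not matched in size to the observed ones. On average they gained 650.4 regions in shALKBH5 and 648.6 in shFTO, against 506 and 654 observed. Taking other pairs of lists as the common control gave 26 to 494 shared regions, and 7 of the 14 such pairs gave at least as many. With the same number of top-ranked peaks per list, 191 regions were gained in both. Simulated lists shared 122 (102 to 146), and other control pairs gave 65 to 176, 0 of which gave as many. In this setting the simulated lists gained 492.6 and 496.7 regions on average, fewer than the 551 and 673 observed. The excess over the simulation may therefore reflect longer lists. Part of any excess over independence may come from the shared controls, which the simulated lists have as well. A comparison with a separate shGFP list for each knockdown was not run. With 1 list left out, the shared count was 517 and 412 without shGFP replicates 1 and 2, 373 and 204 without shALKBH5 replicates 1 and 2, and 347 and 169 without shFTO replicates 1 and 2.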

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

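The tests against a fold change of 2, without chromosomes 8 and Y, without genes overlapped on the opposite strand and with D395A peaks at a q below 0.05 were chosen after the result was seen. Across the scaling, filter, test, replicate block and leave-one-out alternatives, 10347 to 13994 genes were called in D395A against WT, within 1.5 times 12643. The replicate block called 12895, with a correlation of 0.034 between same-numbered replicates, whose numbers were not taken as pairs. Against a fold change of 2, a stricter null, 4027 genes were called, with 1294 lower. Without overlapped genes, 1931 genes were at least 2-fold higher. Of the values of named genes over the settings, 1706 kept their direction and call, 35 no longer passed against a fold change of 2, and Mettl3 passed without D395A replicate 2.

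With camera 2 lists were called, and with an estimated correlation 0. With fry, which tests each list against no change and not against other genes, 14 were called, and there the formative and primed epiblast list also changed direction (adjusted p = 0.049). With a replicate left out, 2 to 4 lists were called. The RNA difference of WT-only peak genes, 0.033, was -0.051 with exon assignment, -0.183 without covariates and -0.106 without overlapped genes, and -0.006 to 0.086 with a replicate left out, negative without WT replicate 2. That of genes with peaks in both lists, 0.239, was 0.077 with exon assignment, -0.339 without covariates and 0.048 without overlapped genes, and that of genes with a D395A peak only, 0.254, was 0.04, -0.287 and 0.03 in these settings. With D395A peaks at a q below 0.05 the differences were 0.067 ± 0.033 for WT-only genes, 0.244 ± 0.051 for genes with both and 0.418 ± 0.072 for D395A-only genes. The cause was not tested for any of these.

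In the mouse lists, 2.12% of WT peaks were overlapped and 12335 genes held WT peaks alone with D395A peaks at a q below 0.05, where fewer peaks enter. The overlap was 9.5% in the best-ranked 50% of each list, 11.56% at the same number of top-ranked peaks and 3.31% with 50% of the peak covered, and the cause was not tested. In HEK293T cells the best-ranked 50% of each list gave 204 gained and 369 lost regions in shALKBH5, 288 and 328 in shFTO and 67 gained in both, from fewer peaks. With 1 list left out, a region needs fewer lists, and gained regions ran from 1157 to 3143 and lost from 1312 to 2981 in shALKBH5, from 1221 to 4165 and from 903 to 2471 in shFTO, and shared from 169 to 517. The motif test of m6A sites was not run, as no genome sequence was at hand.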

Other observations

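The test of WT peaks removed from their list and both tests of opposite-strand genes were chosen after the result was seen. Beyond the lists given above, immediate early genes held a WT peak in 17 of 19 cases and a D395A peak in 6, interferon response genes in 11 and 3 of 23, and mesoderm genes in 11 and 3 of 18. Glycolysis genes held them in 13 and 19 of 23 cases. None of these counts was adjusted for RNA level, which differed between the peak classes. With D395A peaks at a q below 0.05, a choice also made after the result was seen, the D395A counts of these lists were 1, 0, 0 and 15 in that order. After the Mat2a peak, the most significant D395A peaks lay in Ston1, an endocytic adaptor gene (mm10 chromosome 17, 88643057 to 88644399, fold enrichment 64.9), and in Ust, a sulfotransferase gene (chromosome 10, 8348256 to 8349487, 48.0). Neither overlapped a WT peak, nor did any other of the 20 most significant D395A peaks. These also lay over Gm26917 on chromosome 17, Erdr1, Malat1 and the mitochondrial genome. The WT list held 0 mitochondrial peaks and spanned 21 chromosomes and contigs, against 5 peaks and 30 in the D395A list. Of 15 mitochondrially encoded genes, 0 held a WT peak and 9 a D395A peak. Absence from the WT list thus does not show that a peak is particular to D395A.

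WT and D395A m6A peaks overlapped little, with 10.1% of WT peaks shared. Lower exonic RNA-seq counts in D395A are argued against as the whole cause. The test took WT peaks in genes with a log2 fold change of at least -0.25 and a D395A mean of at least 10 CPM. Of these peaks, 13.1% were overlapped (exact interval 12.6 to 13.7), and 23.9% with every missing peak beside a D395A peak added, counted in gaps between WT peaks. The immunoprecipitation used chromatin RNA, whose level was not compared here, and 29.9% of WT peaks lay in introns. Lower RNA in that fraction therefore stays open. Among the 1000 most significant WT peaks 23.0% were overlapped, but since 5369 numbered WT peaks are missing, lower depth of the D395A pair cannot be told apart. Methylation next to the cap, which METTL3 does not make, may add to the D395A list, as summits near transcript starts were 6.0 times as frequent (5.06 to 7.11) among its peaks with a q below 0.05 outside the WT list as among WT peaks not overlapped, though only 173 of 1124 placed summits lay there. The excess was not particular to peaks outside the WT list. D395A peaks at that q that overlap a WT peak had 9.9% of summits there, against 3.6% of WT peaks overlapped in D395A. Removal of WT peaks before deposit may also contribute, since the strongest D395A peaks lay in gaps of WT numbering 5.21 times as often as weak ones (4.59 to 5.93; 71.0% against 13.6%, where these gaps are 29.1% of the length between WT peaks), and loss of METTL3 catalysis, the difference the design names, stays open and untested.

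RNA from chromosomes 8 and Y was lower in D395A, and that from chromosome 6 was higher, which was not tested further. A few strongly changed genes are argued against as the cause on chromosome 8, where the difference was -0.317 (log2) without genes changed 2-fold. A difference in copy number of chromosome 8 between the lines, in all cells or some, may underlie it, since 100% of its windows lay below the other autosomes. The difference of -0.38 with all compared genes was smaller than the -0.585 (log2) of 2 copies against 3 in every cell. Complete loss of chromosome Y is argued against by Eif2s3y, Ddx3y and Uty, which kept 16.9%, 22% and 22.7% of their WT level. Kdm5d, at only 3.76 CPM in WT, stood at 159%. Loss in part of the cells stays open, though it alone would not raise Kdm5d. An effect of the METTL3 substitution itself also stays open and untested.

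Genes overlapped on the opposite strand had higher counts in D395A, and both tests below used those with at least 50% overlap and under 1 CPM in WT. The CPM of the overlapping gene is scaled here to the overlapped share of its exonic bases. Transcription unrelated to the level of the overlapping gene is argued against, as the median CPM where that gene is under 1 CPM was 0.21% of that where it is at 30 CPM or more. Reads of the overlapping gene counted on the wrong strand in the D395A libraries may be a source, since the median rose 24.4 times from partners at 1 to 3 CPM to partners at 30 CPM or more. Antisense transcription that follows the level of the overlapping gene was not tested and stays open.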
